A study of Mus musculus with 6 samples.

How the data were processed

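Corneas of 2 groups of mice, OFBI and Naive, were compared, with 3 libraries per group, each a pool of corneas. Per the labels' protocols, total RNA was isolated with RNeasy columns and 2 µg per sample went into a stranded library kit. Per the series' design text, libraries were sequenced on an Illumina NovaSeq platform. The submitters' processing notes name GRCm38, FastQC, HISAT2, StringTie and DESeq2, with no version, role or order. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here.

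The authors deposited 1 table per library with estimated counts per gene, as whole numbers that were not scaled for depth. The unit was read from the values: the totals differ between libraries, values of 1 to 3 are rare and multiples of 4 are frequent, as for counts derived from transcript coverage. About 4 counts then stand for 1 fragment, which is an inference from the values and not stated by the authors. Multiples of 4 made up 39.4% to 50.4% of the values from 1 to 40. If it holds, count models see more precision than the fragments give for genes with few counts, and dividing the counts by 4 was tried as an alternative. The 6 tables listed the same 22040 rows. Rows that shared a symbol were summed, 64 rows on 31 symbols, which left 22007 symbols. Of these, 26 were rows whose gene names had turned into dates. They held at most 0.148% of the counts of a library and were kept under neutral names.

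Genes were tested with edgeR 4.0.16 in R 4.3.3, on the deposited estimated counts, which needed no rounding. The filterByExpr filter, TMM scaling, a quasi-likelihood fit with group as the only term and Benjamini-Hochberg adjustment were used, two-sided, with a threshold of 0.05. TMM factors ranged from 0.916 to 1.08. The SE of a log2 fold change was its size divided by the square root of the F statistic. Gene lists and Reactome pathways, the latter from fgsea 1.28.0, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, for lists with at least 5 tested members and pathways with 15 to 300. Estimated correlations and the fry test were alternatives. Of fry's p-values, the directional one was used. CPM values are scaled by TMM, with means ± SD over 3 libraries.

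The tests, the 34 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule took 3 kinds of genes. The first were the 6 largest rises and the 6 largest falls among genes with an adjusted p below 0.05, a log2 fold change of at least 1 in size, a mean CPM of at least 5 and groups that did not overlap, without predicted genes and receptor or antibody segments. The second were the 2 tested members with the smallest p in each of 22 core lists. The third were the 2 most abundant tested members in each of 3 quality lists and 9 lists of other tissues. The neutrophil list had 4 tested members and is given as counts only. Coordinates are those of GENCODE mouse release 21 on GRCm38, 1-based and for the whole gene, and 21837 symbols matched that annotation by name. It may not be the release the authors used. Values of a few genes that the rule took are not reported here.

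A group at 0 was given a floor of 12 deposited counts, or 3 fragments, over the summed libraries of the group, and folds against it are lower bounds. Floors cover counting error only, since the libraries carry no molecular identifiers known here. The Naive libraries held 41971752 to 47809779 and the OFBI libraries 1173472 to 3410476 estimated counts. A floor of 12 counts is 0.251 to 0.286 CPM in a Naive library and 3.52 to 10.2 CPM in an OFBI library. No pair of libraries in a group agreed within sampling noise, with a mean chi-square per gene of 4.43 to 15.4, so all were counted as separate samples.

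The procedure was tested on simulated data with the real means and library sizes, on 13490 genes with 200 genes changed in each of 3 simulations. For the OFBI against Naive comparison it called 69.7% of 4-fold and 12.0% of 2-fold changes, and 1.61% of its calls were false. Only the more abundant genes were changed, both groups had the same dispersion and no GC trend was simulated. These rates may thus not hold for the real calls, of which the lower genes had a median mean CPM of 3.70. A raised list was called, and 0 of 20 null lists were.

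The alternatives fixed at that point were DESeq2 1.42.0, limma-voom, DESeq2 size factors, upper quartile factors, library size only, no filter, a filter of 1 CPM in 3 libraries, a replicate block, a threshold of 0.01, a minimum fold of 1.5, removal of the 10 most abundant genes and leaving out each library in turn. Restricting the genes to those in all files was moot, since all files list the same genes. Thinning the Naive libraries or all libraries, dividing counts by 4 and removing a GC and length trend were added after the data were seen. Lists for hepatocytes, cardiomyocytes, brain neurons, kidney tubule, exocrine pancreas, testis germ cells, lung epithelium and further T cell signalling genes were also added then. Figures were drawn with matplotlib 3.10.9. No library was left out of the main comparison.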

Results

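RNA was measured in corneas of male C57BL/6J mice 12 months after an open-field blast injury (OFBI) and in corneas of Naive mice with the same 12-month label. The injury was a single detonation of 350 g of the plastic explosive C-4 at a distance of 3 m from awake animals. Each group had 3 libraries, and each library was made from a pool of corneas that the series describes as a biological replicate. The series title names immune and extracellular matrix genes, so the comparison of OFBI with Naive asks which of these, and which other genes, differed 12 months after the blast.

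The libraries differed widely in depth, and the difference followed the groups. The Naive libraries held 47809779, 43053764 and 41971752 estimated counts, and the OFBI libraries held 3410476, 3355422 and 1173472. The mean depth of the Naive group was 16.7 times that of the OFBI group. Counts above 0 were found for 72.3% to 72.8% of genes in the Naive libraries, for 57.4% and 56.2% in OFBI replicates 1 and 2, and for 47.0% in OFBI replicate 3. Pearson correlations of log2 CPM were 0.982 to 0.988 between Naive libraries, 0.758 to 0.846 between OFBI libraries and 0.744 to 0.861 across the groups. The first principal component, with 63.8% of the variance, followed the order of depth. OFBI replicate 3 lay at -287, OFBI replicates 1 and 2 at -4.6 and -9.3, and the Naive libraries at 99.3 to 101. No batch comparison was possible, since all 6 libraries carried batch number 4.

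**Figure D1:**
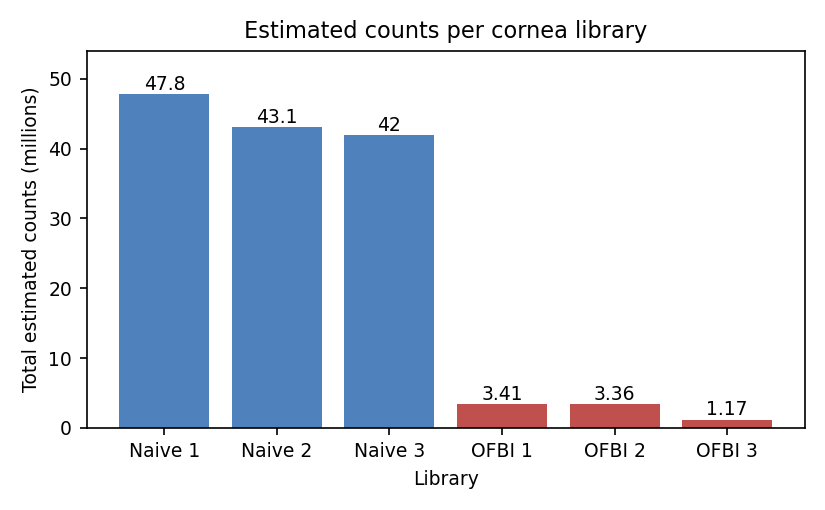
Total estimated counts, 1 bar per library, Naive in blue and OFBI in red. The Naive libraries lie between 41971752 and 47809779 and the OFBI libraries between 1173472 and 3410476.

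After OFBI, 11 of 20 stromal collagen genes and 13 of 18 lymphocyte genes were called higher, as were the elastin gene Eln, the keratin gene Krt14 and the albumin gene Alb, while the decorin gene Dcn was called lower. As sets, neither the collagens nor the lymphocyte genes were called with an estimated correlation (camera adjusted p = 0.18 and 0.56). The counts of Alb, and those of the lymphocyte genes summed over the list, did not follow depth. Of 13941 genes tested, 1173 were higher and 1446 were lower in OFBI than in Naive corneas (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). A fitted fold of at least 2 was reached by 815 of the higher and 1170 of the lower genes, the latter including all 742 that were at 0 in every OFBI library, of which 126 lay at least 2-fold above the OFBI floor. The smallest adjusted p was 0.0053, and 4589 genes had an unadjusted p below 0.05. The values of the groups did not overlap for 6467 genes, or 46.4%. Chance gives 10% for 3 against 3 libraries of like depth and noise. Depth followed group here, so the excess over 10% cannot be told apart from an effect of depth. The higher genes had a median mean CPM of 73.7 and the lower genes one of 3.70. For 400 of the 742 genes the Naive level was at or under that floor of 1.62 CPM, the level that 3 fragments over the 3 OFBI libraries would give at 4 counts per fragment. A difference in these 400 genes was not detectable at the OFBI depth. The remaining 1046 lower genes still include genes at 0 that lie under 2-fold above the floor. With the Naive libraries thinned to the depth of OFBI replicate 1, 1082 genes were higher and 579 lower. With all libraries thinned to that of OFBI replicate 3, 907 were higher and 437 lower. Without Naive replicate 1, 2 or 3 the edgeR test called 106, 0 and 104 genes, with 2611, 2441 and 2615 genes at an unadjusted p below 0.05, while DESeq2 called 1988, 1537 and 1797 genes and limma-voom 2089, 1566 and 1900. With library size as the only scaling, 29.8% of the changed genes were higher, against 44.8% with TMM, and the median log2 fold change of all genes was -0.40 instead of -0.20.

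The rule for naming genes took 62 that passed the edgeR test with all 6 libraries. Without Naive replicate 1, 2 or 3, 57 of the 62 were tested, and 10, 0 and 9 of them passed, while all 57 had an unadjusted p below 0.05 each time. Without OFBI replicate 1, 2 or 3, 56, 57 and 60 passed. Genes given without a value of their own were chosen after their values were seen. A gene called lower by edgeR, at 0 in all OFBI libraries and with a Naive level at or under 1.62 CPM is said to be under the OFBI floor, and its difference was not detectable at this depth. Counts adjusted over the list alone are given where they differ from those adjusted over all genes.

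The 6 largest rises among genes with a mean of at least 5 CPM and groups that did not overlap were Erv3, Mup1, Mup11, Alb, Mup7 and Mat1a. Alb, the gene of serum albumin (chromosome 5, 90460897 to 90476602, GRCm38), had 269 ± 326 CPM (SD, n = 3) after OFBI and 1.92 ± 1.93 CPM (SD, n = 3) in Naive corneas. Its log2 fold change was 7.10 (SE 1.28, edgeR adjusted p = 0.0179). Its counts did not follow depth, with 197, 318 and 689 in OFBI replicates 1, 2 and 3. Over 21 hepatocyte markers, a list added after the data were seen, the median log2 ratio of counts in OFBI replicate 3 to the mean of replicates 1 and 2 was 1.13, where depth gives -1.53. The major urinary protein genes Mup1, Mup7 and Mup11 encode liver-made pheromone carriers and had log2 fold changes of 8.04, 7.04 and 7.27. They are near-identical copies, so counts may be split between them and each value is uncertain. Mat1a, the liver form of methionine adenosyltransferase, had a log2 fold change of 6.87 (SE 1.67). Erv3 had estimated counts of 28, 16 and 187 in OFBI replicates 1, 2 and 3 and 5, 0 and 0 in the Naive replicates. Without OFBI replicate 3 the log2 fold changes of Alb, Mup1, Mup7, Mup11, Mat1a and Erv3 were 5.40, 6.08, 6.34, 5.38, 4.61 and 7.47, and all 6 passed. Without Naive replicate 3 those of Alb, Mup1, Mup7 and Mat1a were 8.37, 8.90, 8.12 and 7.87 (edgeR adjusted p = 0.0601, 0.0863, 0.0800 and 0.127). Without Naive replicate 1 the Naive counts of Erv3 were 0, so no fold is given. The SD between OFBI pools was larger than the mean for Alb, Mup1, Mup11, Mat1a and Erv3.

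The 6 largest falls under the same conditions were genes at 0 in every OFBI library. Against the floor of 3 fragments over the OFBI group, Wdr74, a factor of ribosome assembly, was at least 8.99-fold lower, Thnsl2 at least 7.87-fold, and Npy, which encodes neuropeptide Y, at least 7.6-fold. Syt16, Cst6 and Zfp867 were at least 7.53-fold, 6.78-fold and 5.94-fold lower. Cst6 encodes cystatin E/M, an inhibitor of cysteine proteases. In Naive corneas these genes had 9.57 to 14.6 CPM. The bounds hold for counting error alone.

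More stromal and fibrillar collagen genes were called higher than lower after OFBI. Of 20 stromal and fibrillar collagen genes tested, 11 rose, 2 fell and 7 did not pass the test, with a median log2 fold change of 1.48. Adjusted over the list alone, 13 rose and 2 fell. Col3a1, which encodes type III collagen (chromosome 1, 45311538 to 45349706), went from 24.4 ± 5.86 to 198 ± 42.2 CPM (SD, n = 3), a log2 fold change of 3.02 (SE 0.26, edgeR adjusted p = 0.0053). Col16a1 (chromosome 4, 130047840 to 130099283) went from 64.5 ± 6.29 to 266 ± 50.3 CPM (SD, n = 3), a log2 fold change of 2.04 (SE 0.18, edgeR adjusted p = 0.0054), and of 1.31 with a GC and length trend removed (edgeR adjusted p = 0.0134). The 2 that fell were Col12a1 and Col8a1. As a set the collagens lay above other genes (camera, adjusted p = 1.2e-10), a call that was lost with an estimated correlation, where adjusted p = 0.18. Without Naive replicate 1, 2 or 3, 4, 0 and 6 collagen genes rose by edgeR, 12 each time had an unadjusted p below 0.05, DESeq2 called 12, 11 and 12, and limma-voom called 11 each time.

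Other matrix groups were mixed. Among 21 keratocyte and small proteoglycan genes, Thbs4 rose and 3 fell, with a median log2 fold change of -0.35 (camera adjusted p = 0.67). Decorin, Dcn (chromosome 10, 97479609 to 97518143), a proteoglycan that binds collagen fibrils, went from 118 ± 3.13 to 42.1 ± 16.6 CPM (SD, n = 3), a log2 fold change of -1.46 (SE 0.27, edgeR adjusted p = 0.0187). Chst5, a sulfotransferase that modifies keratan sulfate, had a log2 fold change of -2.29 (SE 0.42). Among 30 basement membrane and hemidesmosome genes, 3 rose, Col7a1, Agrn and Lamb2, and 4 fell, among them Lama1, Lama3 and Col4a4 (3 and 5 adjusted over the list alone, camera adjusted p = 0.67). Col7a1, the anchoring fibril collagen, rose by a log2 fold change of 1.42 (SE 0.17), and by one of 0.72 with a GC and length trend removed (edgeR adjusted p = 0.0303). Of 29 matrix protease and inhibitor genes, 3 rose, Timp2, Mmp15 and Adam10, and 3 were called lower, Adamts5 and, under the OFBI floor, Adamts4 and Adam8 (camera adjusted p = 0.67). Adam10, a membrane sheddase, had a log2 fold change of 1.32 (SE 0.27). Adamts5, an aggrecanase, was at 0 in all OFBI libraries, with a Naive level 2.93 times the OFBI floor.

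Of 36 TGF-beta and myofibroblast genes, 8 rose and 2 were called lower, Fn1 and, under the OFBI floor, Fap (9 and 2 adjusted over the list alone, camera adjusted p = 0.11). The list's median log2 fold change was -0.17, or -0.08 with genes at 0 set to their bound, while its mean was 0.13 and the set test pointed up. Eln, the gene of elastin (chromosome 5, 134702593 to 134747323), went from 13.2 ± 0.84 to 110 ± 38.0 CPM (SD, n = 3), a log2 fold change of 3.05 (SE 0.27, edgeR adjusted p = 0.0054). Tgfb1, which encodes transforming growth factor beta 1, had a log2 fold change of 1.16 (SE 0.17, edgeR adjusted p = 0.0111). With a GC and length trend removed, that of Tgfb1 was 0.30 with an edgeR adjusted p of 0.282, the highest over its alternatives, of which the lowest was 4.2e-09.

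Of 18 lymphocyte genes tested, 13 rose, none fell and 5 did not pass, with a median log2 fold change of 3.93. Adjusted over the list alone, 15 rose and 1 fell. The list has 39 genes, and 5 of the 18 tested reached 1 CPM in every Naive library. A gene low in Naive corneas could thus pass the filter through its OFBI counts. With the Naive or all libraries thinned, 5 and 2 rose, and with a replicate block 2 rose. Thinning left about 11720 and 9706 genes of any kind to test. With all libraries thinned, fewer than 5 genes of the list were tested, so those 2 are not out of 18. Cd2, a T cell adhesion receptor (chromosome 3, 101275899 to 101287939), went from 1.30 ± 0.29 to 31.7 ± 28.6 CPM (SD, n = 3), a log2 fold change of 4.56 (SE 0.74, edgeR adjusted p = 0.0140), and of 3.55 without OFBI replicate 3 (edgeR adjusted p = 0.00446). Zap70, a kinase of T cell receptor signalling, had a log2 fold change of 3.29 (SE 0.51). It rested on few counts, 18, 9 and 4 in OFBI replicates 1, 2 and 3, in the order of depth, and 22, 15 and 22 in the Naive replicates. Summed over the list, the OFBI libraries held 535, 243 and 477 estimated counts and the Naive libraries 1617, 1504 and 1268, against a mean depth ratio of 16.7. The median log2 ratio of counts in OFBI replicate 3 to the mean of replicates 1 and 2 was 0.54, where depth gives -1.53. In the same libraries 16 of 21 hepatocyte and 5 of 14 cardiomyocyte markers were called higher, on lists added after the data were seen. The set call (camera, adjusted p = 1.2e-07) was lost with an estimated correlation, where adjusted p = 0.56. Without Naive replicate 1, 2 or 3 no lymphocyte gene rose by edgeR, 14, 15 and 14 had an unadjusted p below 0.05, DESeq2 called 14, 14 and 12, and limma-voom called 11, 9 and 10.

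Among macrophage genes, 6 of 26 rose and Cd300a was called lower, under the OFBI floor (6 and 2 adjusted over the list alone), with a median log2 fold change of 0.31. With a GC and length trend removed, 2 of the 6 still rose and none was lower. C1qa, a chain of complement C1q, had a log2 fold change of 1.79 (SE 0.38, edgeR adjusted p = 0.0245), and 0.0601 was its adjusted p with a GC and length trend removed, in a range of 3.7e-10 to 0.177 over its alternatives. The set call (camera, adjusted p = 0.043) was lost with an estimated correlation, where adjusted p = 0.56, and without OFBI replicate 2 or 3, where adjusted p = 0.082 and 0.38.

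Of 22 antigen presentation and dendritic cell genes, Tapbp, Ccr7 and H2-K1 rose and Itgax fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.061). Ccr7, a receptor that guides dendritic cells and T cells to lymph nodes, had a log2 fold change of 4.20 (SE 0.74). Its estimated counts were 93, 22 and 40 in the OFBI and 38, 71 and 74 in the Naive libraries. They did not follow the depth difference between the groups. Itgax, the integrin chain CD11c, was at 0 in all OFBI libraries, with a Naive level 1.26 times the OFBI floor. With a GC and length trend removed, Ccr7 still rose and Tapbp and H2-K1 did not pass. Of 22 complement genes, 3 rose and 3 were called lower (camera adjusted p = 0.68). The C1q chains C1qa, C1qb and C1qc rose, Cr1l and Itgax fell, and Masp1 was under the OFBI floor. With a GC and length trend removed, none of the C1q chains passed and 2 genes were lower. Among 26 cytokine, chemokine and receptor genes, none rose and Tnfrsf1a and Il18 fell by edgeR, with Cxcr4 under the OFBI floor, while adjusted over the list alone 0 rose and 0 fell. Tnfrsf1a, a receptor of tumour necrosis factor, had a log2 fold change of -0.59 (SE 0.15). The Naive level of Cxcr4 was 0.751 CPM. Of the neutrophil and granulocyte genes only 4 were tested, and Kit fell.

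Interferon-response genes went both ways, with 4 of 46 called higher and 6 lower, of these Ifi44 under the OFBI floor, and a median log2 fold change of -0.55, or -0.50 with genes at 0 set to their bound (camera adjusted p = 0.19). Ifitm1, an antiviral membrane protein (chromosome 7, 140967221 to 140969825), went from 206 ± 11.7 to 69.0 ± 14.3 CPM (SD, n = 3), a log2 fold change of -1.56 (SE 0.18, edgeR adjusted p = 0.0078). Ifih1, which encodes a cytosolic sensor of viral RNA, had a log2 fold change of -1.76 (SE 0.28).

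Of 40 corneal epithelium genes tested, 10 rose and 7 fell (camera adjusted p = 0.53), and adjusted over the list alone 11 rose and 9 fell. Krt12, the cornea-specific keratin (chromosome 11, 99415666 to 99422259), had a log2 fold change of 1.35 (SE 0.15, edgeR adjusted p = 0.0067), with all 3 OFBI libraries above all 3 Naive libraries. Krt14, a keratin of basal epithelial cells (chromosome 11, 100203162 to 100207548), had 546 ± 7.82 CPM in Naive corneas (SD, n = 3) and a log2 fold change of 1.81 (SE 0.12, edgeR adjusted p = 0.0053). Of 24 limbal and epithelial progenitor genes, 4 rose and 5 were called lower (5 and 6 adjusted over the list alone, camera adjusted p = 0.79), the latter Trp63, Hes1, Atf3, Abcg2 and, under the OFBI floor, Frzb. Krt15, a keratin of basal limbal cells, and Sox9, a progenitor transcription factor, had log2 fold changes of 1.14 (SE 0.14) and 1.01 (SE 0.16). Of 15 cornified envelope genes, Sprr1a rose and Cnfn fell, with Dsc1 and Lce3c under the OFBI floor (2 and 5 adjusted over the list alone, camera adjusted p = 0.60). Sprr1a, a cornified envelope precursor, had a log2 fold change of 1.46 (SE 0.20), and the Naive level of Lce3c was 0.892 CPM.

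**Figure D2:**
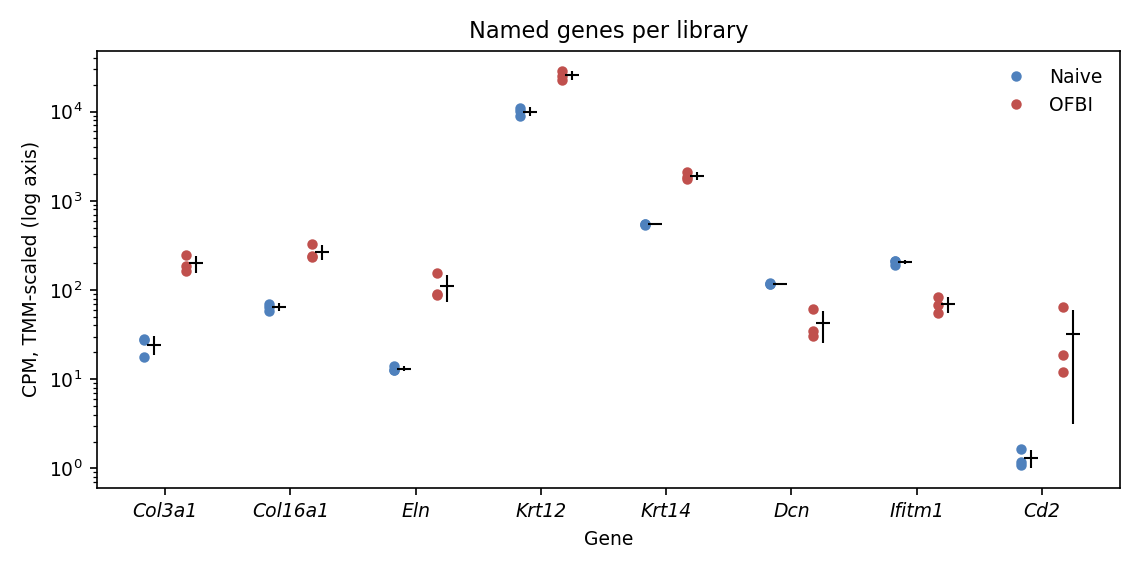
CPM on a log axis, scaled by TMM, of 8 named genes in each library, with Naive in blue and OFBI in red. Black marks give the mean and SD of 3 libraries; Col3a1 rose from 24.4 to 198 CPM and Dcn fell from 118 to 42.1 CPM.

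Among 23 corneal endothelium genes, 3 genes rose, among them Slc4a2 and Foxc1, and 5 were called lower, Aqp1, Tjp1, Col8a1, Slc4a11 and, under the OFBI floor, Slc39a12 (camera adjusted p = 0.80). Aqp1, a water channel, had a log2 fold change of -0.80 (SE 0.13), and Foxc1, a transcription factor of the anterior eye, one of 0.87 (SE 0.15). Of 32 nerve and Schwann cell genes, Nrtn rose and 6 were called lower, of these Mag, Cdh19 and Gap43 under the OFBI floor (camera adjusted p = 0.80). The myelin genes Ncmap and Mag were at 0 in all OFBI libraries. The Naive level of Ncmap was 1.07 times the OFBI floor, and that of Mag was 1.33 CPM. Of 34 blood and lymphatic vessel genes, Flt1 and Notch3 rose and 5 were called lower, Robo4, Reln and, under the OFBI floor, Tek, Angpt1 and Vegfd (4 and 6 adjusted over the list alone, camera adjusted p = 0.80). Reln, which encodes the secreted protein reelin, had a log2 fold change of -2.01 (SE 0.40). Notch3, a receptor of mural cells, had one of 0.69 (SE 0.12), and one of 0.20 with an edgeR adjusted p of 0.253 when a GC and length trend was removed, in a range of 1.3e-09 to 0.309 over its alternatives.

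Among 41 oxidative stress and NRF2 target genes, Gclm rose and 5 fell, Nqo1, Prdx2, Nfe2l2, Mt1 and Mt2 (1 and 2 adjusted over the list alone, camera adjusted p = 0.79). Nfe2l2, which encodes the transcription factor NRF2 (chromosome 2, 75675513 to 75704641), had a log2 fold change of -1.35 (SE 0.19, edgeR adjusted p = 0.0107), and the metallothionein gene Mt2 one of -1.59 (SE 0.27). Of 33 senescence, p53 and DNA damage response genes, Bbc3, Cdkn1b, Igfbp3 and Igfbp7 rose and Plk2 fell, with Pmaip1 under the OFBI floor (camera adjusted p = 0.43). Igfbp7, a secreted binding protein of insulin-like growth factors, had a log2 fold change of 2.17 (SE 0.34), and Bbc3, a pro-apoptotic p53 target, one of 2.55 (SE 0.50), and one of 1.38 with an edgeR adjusted p of 0.0931 when a GC and length trend was removed, in a range of 3.9e-09 to 0.222 over its alternatives. Of 40 cell cycle genes, 2 rose and none fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.95). These were Cdc20 and Aurkb, both regulators of mitosis, with log2 fold changes of 1.57 (SE 0.20) and 1.35 (SE 0.30). That of Aurkb was 2.07 with all libraries thinned to the depth of OFBI replicate 3 (edgeR adjusted p = 0.0308), and its call was lost in 6 of 21 alternatives, with an adjusted p of up to 0.157. Of 43 oxidative phosphorylation genes, Ndufa2 and Ndufv1 rose and Sdhd, Atp5o and Ndufv2 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.86). Ndufv1, of complex I, and Atp5o, of ATP synthase, had log2 fold changes of 1.01 (SE 0.18) and -1.06 (SE 0.23).

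Of 25 retina markers, Guca1a rose and 6 were called lower, of these Opn1sw under the OFBI floor (camera adjusted p = 0.16). Guca1a, a regulator of photoreceptor guanylate cyclase, had a log2 fold change of 1.37 (SE 0.20). Of 19 lens markers, Cryaa, Cryab and Crybb2 rose and Gja3 fell, with Grifin under the OFBI floor (4 and 2 adjusted over the list alone, camera adjusted p = 0.13, and 0.00591 to 0.557 over 18 alternatives), and the crystallin genes Cryaa and Cryab had log2 fold changes of 1.81 (SE 0.21) and 1.66 (SE 0.28). Of 28 skeletal muscle markers, 6 rose and Myh4 and Myh8 fell, with Mylk2 under the OFBI floor (camera adjusted p = 0.18), and the most abundant of them, Ttn and Atp2a1, had log2 fold changes of -0.65 (SE 0.31) and -0.35 (SE 0.51) that did not pass the test. Of 21 melanocyte, iris and ciliary body markers, Des and Ttr rose and Tyr, Slc45a2 and Mab21l2 fell, with Six6 under the OFBI floor (camera adjusted p = 0.44), and neither Gpnmb nor Dct passed, with log2 fold changes of -0.17 (SE 0.25) and -1.05 (SE 0.43), though Dct passed without OFBI replicate 3 (-0.69, edgeR adjusted p = 0.0219). Of 11 conjunctiva markers, Krt4 and Krt13 rose and Agr2 was called lower, under the OFBI floor (3 and 1 adjusted over the list alone, camera adjusted p = 0.67). Krt13, a keratin of the conjunctiva, had a log2 fold change of 1.56 (SE 0.16), and Fcgbp one of 0.13 (SE 0.15), which did not pass.

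Of 5 erythrocyte markers, 1 fell (camera adjusted p = 0.13). The alpha globin genes Hba-a1 and Hba-a2 are near-identical, so their split is uncertain, and they had log2 fold changes of -1.85 (SE 0.38) and -1.75 (SE 0.74), of which only that of Hba-a1 passed. Without OFBI replicate 3 that of Hba-a2 passed too (-1.33, edgeR adjusted p = 0.0363). Among 7 adipocyte markers, Pnpla2 and Pck1 rose and Car3 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.64). Car3, a carbonic anhydrase, had a log2 fold change of -2.01 (SE 0.38). Pnpla2, a triglyceride lipase, had one of 0.62 (SE 0.16), with an edgeR adjusted p of 0.14 when a GC and length trend was removed, in a range of 0.000132 to 0.527 over its alternatives. Of 5 lacrimal and meibomian gland markers, Cidea and Fa2h were called lower, both under the OFBI floor (camera adjusted p = 0.90), and of 5 skin and hair follicle markers, Msx2 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.55). Aqp5, Scd1, S100a3 and Dlx3 from these lists did not pass, with log2 fold changes of 0.43, -0.06, -0.08 and -1.0.

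Lists that reflect RNA handling gave a different picture for each class. Of 66 cytosolic ribosomal protein genes, 12 rose and Rpl10 and Rps12 fell, with a median log2 fold change of 0.05. Their set call (camera, adjusted p = 0.035) was lost with an estimated correlation, where adjusted p = 0.80, with library size as the only scaling, where adjusted p = 0.17, and without OFBI replicate 3 or Naive replicate 3, where adjusted p = 0.52 and 0.074. Rps2 had a log2 fold change of 0.81 (SE 0.12), and that of Rpl4, -0.12 (SE 0.14), did not pass. Of 13 mitochondrially encoded genes, mt-Nd6 rose and mt-Nd4l fell (camera adjusted p = 0.55). The gene mt-Nd6 is encoded on the opposite strand from the other protein genes of the mitochondrial genome and had a log2 fold change of 3.01 (SE 0.40). The strand setting of the counting is not given in the sources used here, so mt-Nd6 counts may include reads of its antisense neighbours. The log2 fold change of mt-Co1, -0.44 (SE 0.21), did not pass, but passed without OFBI replicate 3 (-0.71, edgeR adjusted p = 0.00616). Of 26 immediate-early and dissection stress genes, Ier2, Klf2, Jund and Hspa1a rose and Ier3, Dnajb1 and Atf3 fell (camera adjusted p = 0.30). With a GC and length trend removed, 1 gene of that list was higher and 5 were lower. Klf4 and Hspa1b had log2 fold changes of -0.01 (SE 0.23) and 0.00 (SE 0.12), and neither passed. Median, mean and set test also differed in sign, with no call, for the lists of matrix proteases, cytokines, complement, corneal epithelium, limbal, vessel, cell cycle, senescence, oxidative phosphorylation, immediate-early, conjunctiva, lens, skeletal muscle and adipocyte genes.

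**Figure D3:**
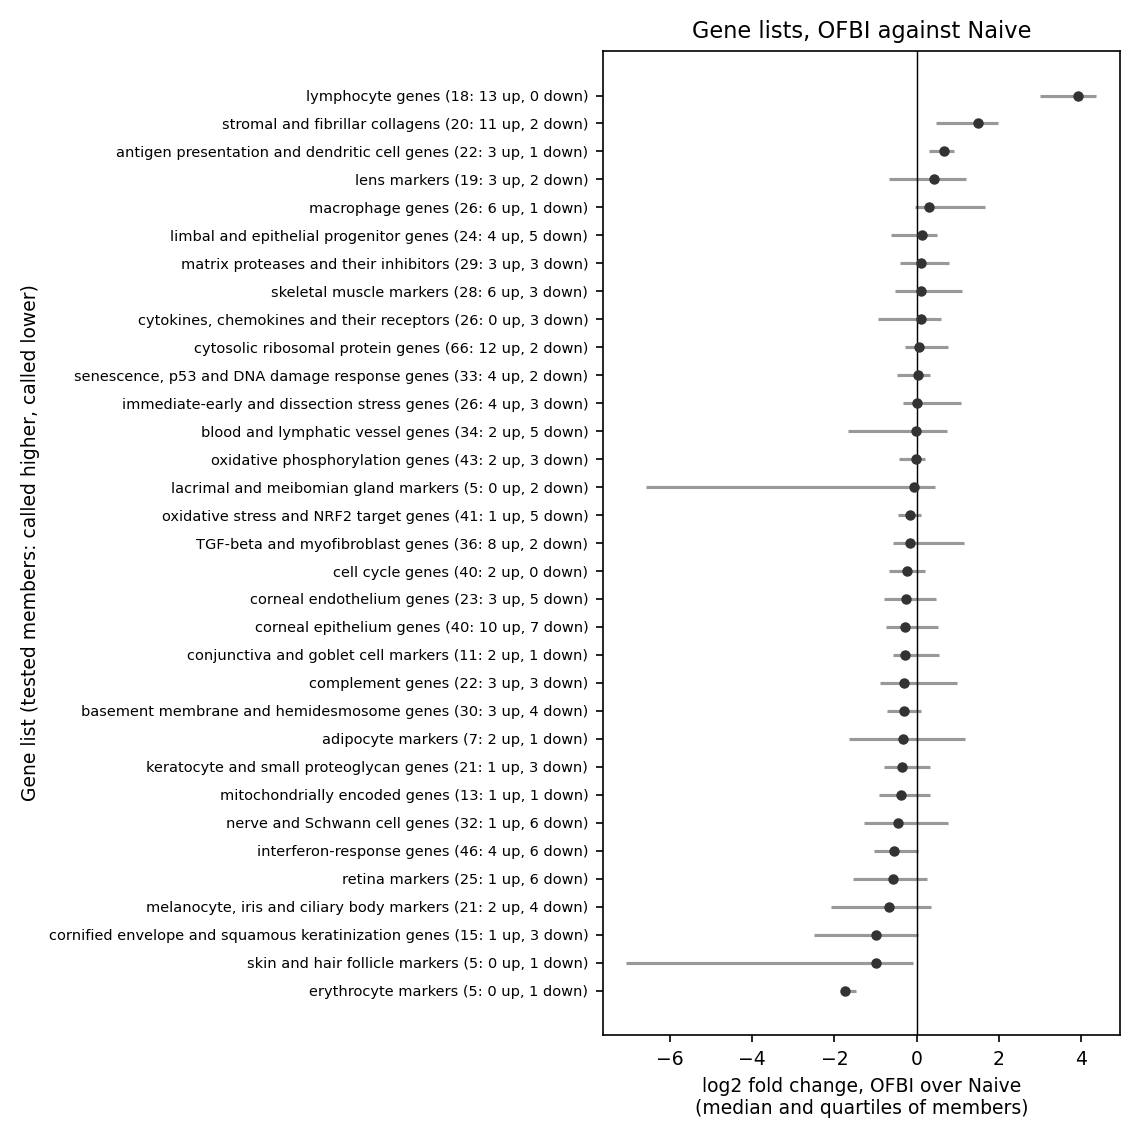
Median log2 fold change, OFBI over Naive, of each of the 33 tested gene lists, with bars from the lower to the upper quartile of the fitted values of its tested members, genes at 0 included, and the number called higher and lower. The lymphocyte list has a median of 3.93 and the collagen list one of 1.48.

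Of 676 Reactome pathways tested as sets, 45 lay above and 2 below other genes (camera, adjusted p below 0.05), and none of these calls held with an estimated correlation. Collagen biosynthesis and modifying enzymes led them, with 15 of 52 genes higher and 3 lower (camera adjusted p = 1.9e-05, and adjusted p = 0.85 with an estimated correlation). Collagen degradation, with 14 of 46 genes higher and 3 lower, is built largely on the same collagen genes. In the set of histone deacetylation, 15 of 44 genes were higher and 2 lower. For second messengers of T cell receptor signalling, 11 of 20 genes were higher and none lower. In striated muscle contraction, 11 of 29 were higher and 1 lower. The overlap of these pathways with the lymphocyte, further T cell and cardiomyocyte lists was not counted, so they cannot be taken as independent support. One of the pathways below other genes was the transport of glucose, other sugars, bile salts and metal ions, with 12 of 60 genes lower and none higher (camera adjusted p = 0.0047, and adjusted p = 0.85 with an estimated correlation).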

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

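Thinning, dividing the counts by 4 and removing a GC and length trend were chosen after seeing the data. In none of the alternatives was a gene that changed with all libraries and settings as planned called in the other direction. The 2619 changed genes, 1173 higher and 1446 lower, became 793, 540 and 253 with a replicate block, 222, 191 and 31 at an adjusted p below 0.01, and 899, 462 and 437 with a minimum fold of 1.5. They became 1661, 1082 and 579 with the Naive libraries thinned to the depth of OFBI replicate 1, and 1344, 907 and 437 with all libraries thinned to that of OFBI replicate 3. Without a low-count filter 910 genes were lower, and with DESeq2 1905 were higher, of which 1172 were among the 1173. DESeq2 gave no adjusted p for 1995 genes. Without each library in turn the edgeR test called 0 to 3676 genes, 0 to 1611 of them higher and 0 to 2065 lower, with the lowest number without Naive replicate 2. With counts divided by 4 it called 1571 higher and 1297 lower, and with a GC and length trend removed 974 and 1196. The cause was not tested. All 6 files list the same genes, so keeping only genes listed in all of them changed nothing.

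Replicate numbers did not pair the libraries: the deviations of libraries that share a number correlated at -0.003, -0.02 and 0.008, and not every library correlated best with its own number. With the replicate block the macrophage call was lost (adjusted p = 0.187), 2 lymphocyte genes rose, 3 lists and 69 pathways were called, and 0.866 and 1.000 were the adjusted p of the cytokine and cell cycle lists, with the direction turned.

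Lymphocyte genes that rose numbered 0 at an adjusted p below 0.01, 7 with a minimum fold of 1.5, 5 and 2 with the Naive or all libraries thinned, and 0 to 16 without each library. With all libraries thinned, fewer than 5 genes of that list were tested. Collagen genes that rose numbered 6 at an adjusted p below 0.01 and 0 to 15 without each library. Of the 33 lists, 0 were called with an estimated correlation and 7 by fry, which tests whether a list's genes move one way and compares them with no other genes. Without each library 4 to 6 lists were called. Of the pathways, 0 were called with an estimated correlation, 27 with a GC and length trend removed and 33 to 52 without each library. With an estimated correlation the adjusted p was 0.182 for collagens, 0.557 for macrophage and lymphocyte genes and 0.799 for ribosomal protein genes. By fry it was 0.0806 for lymphocyte, 0.084 for macrophage and 0.331 for ribosomal protein genes. The ribosomal call was also lost with library size only (0.165), all libraries thinned (0.0727) and counts divided by 4 (0.0767). Without each library the adjusted p ran from 0.00338 to 0.383 for macrophage and from 0.00405 to 0.518 for ribosomal protein genes. Lists without a call gained one as follows. The antigen presentation list was called in 8 of 18 alternatives: library size only (0.0442), without OFBI replicate 2 (0.00405), without Naive replicate 1, 2 or 3 (0.0469, 0.0279 and 0.0354), the Naive or all libraries thinned (0.0268 and 0.0274) and counts divided by 4 (0.0361), with 0.799 the highest. The lens list was called in 6: without Naive replicate 1, 2 or 3 (0.0445, 0.0279 and 0.0365), thinned (0.0268 and 0.00591) and counts divided by 4 (0.0318), with 0.557 the highest. Without OFBI replicate 3 the TGF-beta (0.0336) and mitochondrial lists (0.0163) were called. Besides the collagens, fry called 6 lists, all downward: interferon (0.0161), nerve (0.0343), oxidative stress (0.0308), melanocyte (0.0462), erythrocyte (0.0147) and skin (0.0343). With the GC and length trend removed, the genes that still rose were 2 of 6 in the macrophage list, 1 of 3 in each of the antigen presentation, basement membrane and protease lists, 0 of 3 in complement, 0 of 1 in nerve, 2 of 4 in senescence, 1 of 2 in vessel and in adipocyte, and 1 of 4 in immediate-early genes. The numbers lower went from 4 to 6 for basement membrane, 3 to 5 for immediate-early, 5 to 2 for endothelium and 6 to 4 for retina lists. Over 18 alternatives the collagen adjusted p ran from 1.1e-12 to 0.182, and over 17 that of the lymphocyte genes from 1.0e-10 to 0.557.

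Lists without a call turned direction as follows, with the adjusted p. By fry these were proteases (0.91), cytokines (0.249), complement (0.929), limbal (0.632), vessel (0.221), cell cycle (0.339) and oxidative phosphorylation genes (0.121). Cytokines also turned with upper quartile factors (0.991), the stricter filter (0.851), the Naive (0.841) or all libraries thinned (0.575) and counts divided by 4 (0.61). Cell cycle genes turned with library size only (0.984), thinning (0.862 and 0.904) and counts divided by 4 (0.658), and oxidative phosphorylation genes with library size only (0.919), all libraries thinned (0.904) and counts divided by 4 (0.829). Endothelium genes turned with the Naive thinned (0.988), nerve genes with counts divided by 4 (0.875), melanocyte markers with all thinned (0.747), and vessel (0.935), mitochondrial (0.825) and immediate-early genes (0.878) with the GC and length trend removed. The ranges without each library were 0.398 to 0.913 for keratocyte genes, 0.745 to 0.913 for cytokines and chemokines, 0.467 to 0.981 for corneal endothelium genes, 0.467 to 0.959 for cell cycle genes, 0.878 to 0.99 for oxidative phosphorylation genes and 0.827 to 0.959 for lacrimal and meibomian gland markers.

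Genes without a call turned sign as follows, in log2 fold change. Klf4 turned with upper quartile factors (0.0239), the stricter filter (0.00528), a replicate block (0.0117), the Naive (0.0421) or all libraries thinned (0.0438), counts divided by 4 (0.0213) and limma-voom (2.2e-05). Hspa1b turned with library size only (-0.20), no filter (-0.0140) and the GC and length trend removed (-0.33). With that trend removed Rpl4 (0.0795), Fcgbp (-0.16), Aqp5 (-0.53) and Scd1 (0.18) turned too, Fcgbp also with library size only (-0.0765) and S100a3 with all libraries thinned (0.43). Without each library the ranges were -0.15 to 0.27 for Klf4, -0.11 to 0.0781 for Hspa1b, -0.49 to 0.0231 for Gpnmb, -0.70 to 0.0668 for Atp2a1, -0.17 to 0.0264 for Scd1 and -0.26 to 0.019 for S100a3. The cause was not tested. Over all genes that the naming rule took and all alternatives, 1243 values kept direction and side of the threshold, 276 lost it, 4 passed it and 25 turned sign. The 4 were mt-Co1 (-0.71), Dct (-0.69) and Hba-a2 (-1.33) without OFBI replicate 3, and Dct with counts divided by 4 (-0.88). Over all alternatives the log2 fold change ran from 6.08 to 9.14 for Mup1, 5.38 to 9.03 for Mup11, 6.34 to 8.37 for Mup7, 5.40 to 8.37 for Alb, 4.61 to 7.87 for Mat1a, 1.27 to 2.46 for C1qa, -2.89 to -1.33 for Hba-a2 and -2.38 to -0.55 for Dlx3. At the depth of the libraries, 12 counts are 3.52 to 10.2 CPM in an OFBI library and at most 0.286 CPM in a Naive library.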

Other observations

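The tests in this part were chosen after the results were seen, except the counting-minimum test and the splits for gene lists and pathways. Lists of markers of other organs and of further T cell genes were added after the data were seen, so their counts describe these libraries and are no independent evidence. Of 21 hepatocyte markers tested, 16 rose after OFBI and none fell, with a median log2 fold change of 6.41 (camera adjusted p = 1.1e-10, and adjusted p = 0.38 with an estimated correlation). Alb had 197, 318 and 689 estimated counts in OFBI replicates 1, 2 and 3 and 52, 28 and 188 in the Naive replicates. Of 14 cardiomyocyte markers, 5 rose and Tbx5 was called lower, at 0 in OFBI with a Naive level under the OFBI floor (camera adjusted p = 0.0054, and adjusted p = 0.44 with an estimated correlation). Myh6, the alpha myosin heavy chain of heart muscle, had 240, 4 and 65 counts in OFBI and 14, 59 and 22 in Naive libraries. Of 37 further T cell signalling and activation genes, 31 rose and none fell, with a median log2 fold change of 3.70 (camera adjusted p = 6.7e-21, and adjusted p = 0.38 with an estimated correlation). At least 1 CPM in every Naive library was reached by 3 of the hepatocyte, 5 of the cardiomyocyte and 14 of the T cell signalling genes.

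Of 18 brain neuron markers, 3 rose and 3 were called lower, of these Gad1 and Syn1 at 0 in OFBI with a Naive level under the OFBI floor (camera adjusted p = 0.18). Camk2n1, an inhibitor of a calcium-dependent kinase, had 1021, 1233 and 698 counts in OFBI and 972, 786 and 947 in Naive libraries, a log2 fold change of 4.57 (SE 0.31, edgeR adjusted p = 0.0053). Gnao1, a G protein subunit of neurons, had 655, 702 and 709 counts in OFBI and 938, 898 and 775 in Naive libraries, or 363 ± 260 and 18.3 ± 1.16 CPM (SD, n = 3). Of 9 kidney tubule markers, 3 rose and 3 fell (camera adjusted p = 0.18), and of 6 lung epithelium markers none rose and 2 were called lower, of these Ager under the OFBI floor (camera adjusted p = 0.34). Exocrine pancreas and testis germ cell lists had under 5 tested members and were not tested as sets. Odf2 and Hspa1l, from the testis list, had log2 fold changes of -0.41 (SE 0.30) and 0.56 (SE 1.14). Across 13890 genes, which are not independent replicates, log2 fold change and GC content had a Pearson r of 0.18 and a Spearman rho of 0.31. Of 651 genes below 40% GC, 2.76% were higher and 19.97% lower, and of 69 genes at 65% GC or above, 47.8% were higher and 1.45% lower.

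For the lymphocyte genes a GC and length trend is argued against as the whole cause, since all 13 genes that rose still rose with it removed, with a lower quartile of the log2 fold change over the list of 2.82. A near-equal number of reads from outside the tissue in each library, such as reads of other samples in a shared run, would raise CPM most where depth is lowest. The log2 ratio of counts in OFBI replicate 3 to the mean of replicates 1 and 2 had a median of 0.54 over the list (quartiles -1.04 and 0.76), above the -2.86 to -0.33 of 95% of matched random lists and nearer to the 0 that such reads would give than to the -1.53 of depth. The median also lay above random lists for the further T cell genes (-0.17) and hepatocyte markers (1.13, quartiles 0.43 and 1.65), both raised, but the ratio is not specific, since mitochondrially encoded genes, not raised as a list, had -0.09 (quartiles -0.71 and 0.22). The random lists were matched on mean abundance only. Just 5 of 18 lymphocyte and 3 of 21 hepatocyte genes reached 1 CPM in every Naive library. Genes that passed the filter through OFBI counts may have a higher ratio for that reason, so the random lists cannot decide. Median log2 ratios of OFBI to Naive counts were -0.72 for the lymphocyte, -0.77 for the further T cell and 1.71 for the hepatocyte genes. Depth gives -4.06. The hepatocyte counts were thus not near-equal between the groups, and outside reads in unequal number were not tested. Outside reads stay open for the lymphocyte, further T cell and liver transcripts. Counts of Ccr7, Camk2n1, Gnao1 and Myh6 did not follow depth between the groups either, and outside reads stay open for them too. A lasting presence of lymphocytes after blast, with pools that differ in it, also stays open.

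The stromal collagens behaved otherwise. Their median log2 ratio of counts in OFBI replicate 3 to the mean of replicates 1 and 2 was -1.46 (quartiles -2.21 and -1.11), close to the -1.53 of depth, which argues against a near-equal number of outside reads. With a GC and length trend removed, 10 of the 11 genes that rose still rose, with quartiles of the log2 fold change over the list of 0.40 and 1.67, which argues against that trend as the whole cause. A larger share of corneal stroma in the OFBI pools would raise keratocyte genes as well, and their median log2 fold change was -0.35 (quartiles -0.79 and 0.32) against 1.48 (quartiles 0.46 and 1.98) for collagens. A difference in collagen expression after blast stays open as a hypothesis, as does a library or run difference that goes with group, since every OFBI library was shallow and no label separates depth from group. Only the share of stroma was tested, through keratocyte genes, so a difference in other dissected tissue stays open too.

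Of the tested genes, 831 were at 0 in all OFBI libraries. Counting noise at the lower depth, modelled with the dispersion of the Naive libraries, gives 339.5 such genes. The observed number was 2.45 times that. OFBI libraries correlated less with each other than Naive ones, so their noise may exceed the model. At 3 to 8 expected fragments, Poisson noise gives 1.2% of genes at 0, less than was seen in either group. The ratio thus cannot decide whether noise is the whole cause. A minimum in the counting would act in Naive libraries too, but of genes expected at 3 to 8 fragments 4.37% (exact 95% interval 3.69 to 5.14) were at 0 there, against 17.7% (16.5 to 19.0) in OFBI replicates 1 and 2. At that level 26.1% (23.2 to 29.1) of values were at 0 below 45% GC and 11.04% (9.18 to 13.1) above 55% GC, which is consistent with a GC trend as part of the cause. Fragment numbers rest on 4 counts per fragment, and a true loss of expression after blast stays open, untested.

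The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 2619 genes and the highest of the others 0, with up to 157 genes there at an unadjusted p below 0.05, so 1 split reached the real count. For gene lists the real split called 4 and the highest other 5, and 8 splits called at least 4. For pathways these were 47 and 85, and 3 splits called at least 47. The split with 85 set OFBI replicate 1 with Naive replicates 1 and 2 against the rest, which puts OFBI replicates 2 and 3 with Naive replicate 3.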
